A study of Mus musculus with 4 samples.

How the data were processed

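RUNX1 (a DNA-binding transcription factor of blood development) was mapped by chromatin immunoprecipitation and sequencing in EML cells, a mouse line of multipotent blood progenitors. The 4 libraries were immunoprecipitations with a RUNX1 antibody (RUNX1 1 and RUNX1 2) and with non-specific rabbit IgG (IgG 1 and IgG 2), 2 libraries per group, grouped by their titles. Per the labels' protocols, lysates came from sonicated nuclei and the libraries were sequenced on an Illumina Genome Analyzer. The labels do not say that the libraries of a group came from separate cultures. The p-values of the window tests therefore measure only the spread between these samples, which may be technical. The Poisson p-values of the peaks and the permutation p-values of the chromosomes hold no spread between libraries.

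The deposited files list 1 line per genomic position and strand with a read, and a column with the count of reads stacked there. No file header names that column. Its reading as a count rests on its values, which are whole numbers of 1 or more on lines that do not repeat a position and strand. The reads are 35 bp long, and the genome build is mm9, per the submitters' processing notes. The aligner, its settings and any filter on multiply mapped reads are not given in the sources used here. Reads in repeats, which such a filter decides, can therefore raise or lower counts in ways that were not checked.

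The libraries held 14701321 reads at 9124909 positions (IgG 1), 19761244 reads at 18010514 positions (IgG 2), 20095432 reads at 18485515 positions (RUNX1 1) and 19124931 reads at 17009358 positions (RUNX1 2). In the comparisons 1 read was kept per position and strand, because stacked reads without molecular identifiers can be copies of 1 molecule. IgG 1 lost the most reads this way. Reads were moved towards the fragment centre by 45, 47, 50 and 55 bp in IgG 1, IgG 2, RUNX1 1 and RUNX1 2, from strand cross-correlation lengths of 90, 95, 100 and 110 bp. Exact (Clopper-Pearson) 95% intervals cover counting error only, as does the floor of 3 reads over the group against which a fold is given where no IgG read was present.

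For the comparison of the groups, reads were counted in 500 bp windows. Windows were kept where the mean CPM (reads relative to the library total) of the 4 libraries reached 2 times the genome mean, which left 479201 of 5283702. Counts were scaled by the total of kept reads and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), two-sided, with group as the only term and Benjamini-Hochberg adjusted p at most 0.05. The plan named limma voom as the test and edgeR in its place if the files held a column of counts. They held such a column, so edgeR was used, although the tested counts, with 1 read per position and strand, leave it out. limma 3.58.1 and DESeq2 1.42.0 were run as alternatives. In simulated counts for these 479201 windows, 200 windows were changed. The test recovered 14% of the 4-fold and 97% of the 8-fold changes and made 3 false calls. These counts were drawn with the same spread in every window, so the false calls do not give the error rate on the real counts. Called windows that were higher with RUNX1 and at most 500 bp apart were merged into regions, and the regions named are the 10 with the smallest adjusted p.

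Peaks were called in each RUNX1 library against both IgG libraries pooled. A window of 200 bp, moved by 50 bp, was kept at a Poisson p of at most 1e-05 and at least 4-fold over the highest of the genome, 1 kb, 5 kb and 10 kb IgG rates. The same was done for each IgG library against pooled RUNX1 reads, which gives the background. This test compares libraries, not conditions. Peaks were shared when they overlapped by at least 1 bp. On simulated reads over 200000 steps of 50 bp, the caller found 56% of sites at 8-fold and 99% at 16-fold. It made 2 peaks away from a simulated site. The stretch is a small part of the genome with an even background, so these 2 do not give the error rate on real reads. Random positions for overlaps came from 100 circular shifts within chromosomes. Summit-to-flank ratios divide the reads in 200 bp at the summit by those 5 to 10 kb away, scaled to 200 bp, with 95% intervals from 1000 bootstrap draws over summits. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

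The only gene table used here describes assembly GRCm38.p6, not mm9. It served to count protein-coding genes per chromosome, and none of its coordinates was set against a peak. The planned tests of promoters, positions relative to genes, RUNX motifs and gene lists need the mm9 annotation or sequence and were not run. No gene is named for a region for the same reason. The alternatives covered the scaling, the filter, the window size, stacked reads, the read shift, the test, the replicate block, each library left out in turn, and the threshold, overlap, control and depth of the peak calls. These choices were listed before the data were examined. A crossed replicate block and thinning to the depth of IgG 1 were added after seeing the data, as were the simulation with a drawn control and the chromosome, cluster and summit comparisons.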

Results

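Occupancy of RUNX1 across the genome of EML cells was measured in 4 sequencing libraries, 2 with RUNX1 antibody and 2 with IgG as the control for non-specific recovery. The kept depth was 18485515 and 17009358 read positions in RUNX1 1 and RUNX1 2, and 9124909 and 18010514 in IgG 1 and IgG 2. In IgG 1, 61.6% of positions had been read once, against 91.4% in IgG 2, 92.4% in RUNX1 1 and 89.4% in RUNX1 2. IgG 1 therefore gave the least precise counts. The IgG libraries were also the least alike pair. Over 10 kb bins their log2 CPM correlated at 0.818, against 0.839 for IgG 1 with either RUNX1 library and 0.909 for RUNX1 1 with RUNX1 2. Over the tested windows the correlation was -0.093 for the IgG pair and 0.465 for the RUNX1 pair. The cause was not tested. All positions are in mm9.

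The first comparison asked where RUNX1 reads exceeded IgG reads by more than the spread between the libraries of a group. edgeR pooled that spread over the tested windows (common coefficient of variation 0.24) and gave no weight to a window's own spread. A window in which the libraries of a group differed widely could therefore still be called. In 1594 windows of 500 bp the RUNX1 libraries were higher, and in 39 they were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at most 0.05). Each of the 1594 windows had a higher CPM in both RUNX1 libraries than in both IgG libraries, which the selection by the test favours. They merged into 1578 regions with a median pooled fold of 9.17 (interquartile range 7.80 to 11.2), counting the 5 regions with no IgG read at their lower bound. These folds are those of windows that passed the test. Peaks found in both RUNX1 libraries overlapped 20173 tested windows by at least 1 bp each. Called or not, these windows had a median log2 fold change of 1.63, which their parts outside the peaks can lower. In the tested windows elsewhere the median was 0.02. Of the 1578 regions, 1330 (84.3%) overlapped a peak found in both RUNX1 libraries, and 57 overlapped a peak of neither. Those peaks had been chosen for a 4-fold excess over the same IgG reads. Neither the median of 1.63 nor this overlap is therefore independent evidence.

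Of the 14141 peaks found in both RUNX1 libraries 1338 (9.46%) overlapped a called region by at least 1 bp. The number of called windows depended on the test. limma voom, which the plan named first, called 0 windows higher and 0 lower. It had 44727 higher and 10591 lower at an unadjusted p under 0.05. DESeq2 called 2999 higher and 0 lower, and limma trend 5157 and 110. In edgeR, scaling by the median ratio over 10 kb bins gave 599 and 13, TMM gave 2436 and 69, no filter gave 332 and 6, and a filter at 4 times the genome mean gave 0 and 0 (11606 and 33 at an unadjusted p under 0.05). Windows of 200 bp gave 199 and 0, and windows of 1000 bp gave 700 and 2. edgeR called 188 higher without IgG 1, and 0 higher without IgG 2, without RUNX1 1 or without RUNX1 2, where 20827, 16051 and 9565 were higher at an unadjusted p under 0.05. With the replicate number as a block 25 were higher.

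The windows with the smallest adjusted p had no IgG read, so each fold is given against the floor of 3 IgG reads, with the exact 95% lower limit for 0 IgG reads beside it. At chromosome 15, 60668001 to 60668500, RUNX1 1 held 14 reads and RUNX1 2 held 31, a mean of 1.29 ± 0.75 CPM (SD, n = 2) and at least 11.5-fold higher than IgG at the floor (exact lower limit 8.95). A window on chromosome 13, 16028001 to 16028500, held 21 and 29 reads with RUNX1, at least 12.7-fold higher (9.98). On the same chromosome, 19763001 to 19763500 held 20 and 19 reads, at least 9.94-fold higher (7.71). On chromosome 1, 54050501 to 54051000 held 14 and 21 reads, at least 8.92-fold higher (6.88). The adjusted p of the quasi-likelihood test in edgeR was 0.00047 for the first 3 of these and 0.00067 for the fourth.

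The fifth region, on chromosome 1 from 38751001 to 38751500, was the one of the 10 with the most reads. It had 156 and 239 RUNX1 reads against 8 and 9 IgG reads, which is 11.2 ± 4.0 CPM against 0.688 ± 0.267 CPM (SD, n = 2 each). The fold was 17.8 (95% interval 10.95 to 30.80) and the log2 fold change 4.07 with a standard error of 0.75 (edgeR adjusted p 0.0028). The other 5 regions had 1 IgG read each, all in IgG 2. They began at 84497501 on chromosome 18, 21015501 on chromosome 1, 9302501 on chromosome 3, 77563501 on chromosome 15 and 19610001 on chromosome 13. Their folds lay between 33.6 (95% interval 5.73 to 1358) and 42.0 (7.24 to 1691). They rest on 1 IgG read, below the floor of 3 used above, so they cannot be set against the folds there. IgG 1 and IgG 2 had genome means of 0.691 and 1.36 reads per 200 bp, so 1 read in 500 bp was below average. The order by p favours such windows and those with no IgG read, so their folds can be too high. All 10 regions overlapped a peak found in both RUNX1 libraries. None of the 10 passed the threshold of edgeR without IgG 2, without RUNX1 1 or without RUNX1 2, nor that of limma voom, and 8 of the 10 did not pass in 200 bp windows. The fifth region also lost its call in edgeR without IgG 1 (adjusted p 0.579), with the replicate block (0.615) and with the filter at 4 times the genome mean (0.0622). The regions beginning at 9302501 on chromosome 3 and 77563501 on chromosome 15 lost theirs with the replicate block (edgeR adjusted p 0.0689). They also lost theirs with that filter (edgeR adjusted p 0.0622). The first region, at 60668001 on chromosome 15, lost its call in 1000 bp windows (edgeR adjusted p 0.0505). Its log2 fold change was 2.03 there against 7.33 in the main fit.

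Among regions with the most RUNX1 reads, which were chosen after their values were seen, chromosome 1 from 140033001 to 140033500 had 12.1 ± 4.3 CPM with RUNX1 and 0.993 ± 0.009 with IgG (SD, n = 2 each). The fold was 12.0 (95% interval 8.15 to 18.5). Chromosome 14 from 54847001 to 54847500 had 11.5 ± 5.6 CPM against 0.769 ± 0.617, an 18.1-fold difference (11.1 to 31.3). Chromosome 7 from 35941501 to 35942000 had 10.6 ± 1.8 CPM against 0.634 ± 0.033, a 16.9-fold difference (10.4 to 29.3).

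The windows lower with RUNX1 were few. In 23 of the 39 IgG 1 was more than 2 times IgG 2 in CPM. The one with the smallest p, on chromosome 6 from 125827001 to 125827500, had 38 reads in IgG 1, 2 in IgG 2, 1 in RUNX1 1 and 2 in RUNX1 2. Without IgG 1, edgeR called 0 windows lower, with 6089 lower at an unadjusted p under 0.05. It called 45 without IgG 2, and 0 without RUNX1 1 or without RUNX1 2, with 6411 and 4035 lower at an unadjusted p under 0.05.

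Each RUNX1 library was then searched for peaks on its own, to ask which sites appeared in both. RUNX1 1 gave 21540 peaks and RUNX1 2 gave 31012. Of these, 14141 peaks of RUNX1 1 (65.7%) overlapped a peak of RUNX1 2, and 14070 peaks of RUNX1 2 (45.4%) overlapped a peak of RUNX1 1. With the antibodies exchanged, IgG 1 gave 2995 peaks and IgG 2 gave 3109 over the RUNX1 background, and 35 were shared. IgG 1 had fewer kept reads than the other libraries, so its count is not at like depth. With the tested libraries thinned to the depth of IgG 1, RUNX1 1 and RUNX1 2 gave 11244 and 20582 peaks. At that depth IgG 1 and IgG 2 gave 2995 and 1267. Circular shifts of the peaks gave a mean overlap of 173.07 peaks and at most 208 in 100 draws.

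**Figure D1:**
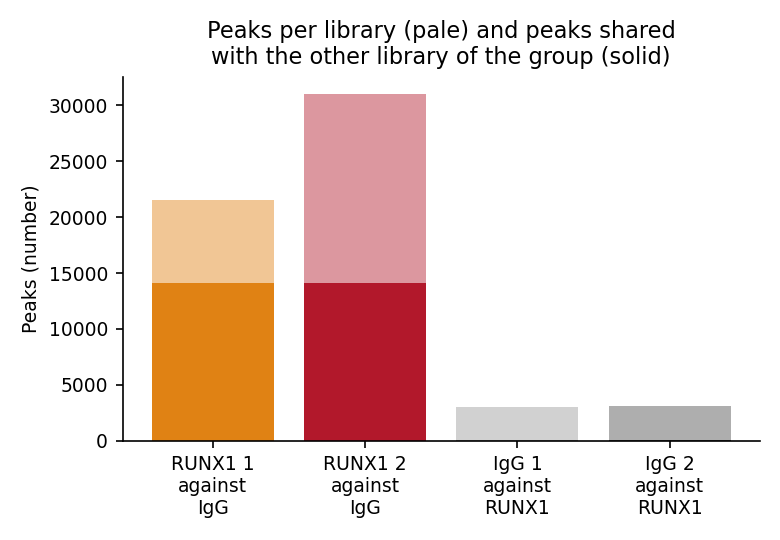
Number of peaks (vertical axis) in each library against the pooled libraries of the other antibody (horizontal axis), with peaks shared by the other library of the same antibody in solid colour and the rest in pale colour. The RUNX1 libraries gave 21540 and 31012 peaks with 14141 and 14070 shared, and the IgG libraries gave 2995 and 3109 with 35 shared.

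Both sets of RUNX1 peaks used the same pooled IgG, so part of the overlap may come from the shared control. When both RUNX1 libraries and their common control were drawn anew from the 10 kb IgG rate, with no sites added, they had means of 97.8 and 101.2 peaks and shared 0 in each of 5 draws. These draws hold the chance counts of a shared control but none of the real unevenness of IgG below 10 kb. With a separate IgG library for each RUNX1 library, 11667 peaks were shared when IgG 1 was set against RUNX1 1 and IgG 2 against RUNX1 2, and 13827 the other way round. Peaks with small p recurred most. All of the 1000 peaks of RUNX1 1 with the smallest p and 99.9% of those of RUNX1 2 were found in the other library, and for the first 10000 by p the shares were 94.3% and 81.7%. At a p of at most 1e-08 the libraries kept 10269 and 19481 peaks, and 9036 were shared.

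The shared peaks were narrow, with a median width of 350 bp (interquartile range 250 to 400). Their median fold over the IgG rate was 6.64 in RUNX1 1 and 9.45 in RUNX1 2, and 2535 reached 10-fold in both. At 13906 of the 14141 the summit had a higher CPM in both RUNX1 libraries than in both IgG libraries, and at 110 no IgG read was present. The peaks had been chosen for a 4-fold excess over IgG, so these counts are no independent evidence of it. The peaks covered 0.181% of the genome and held 2.45% of the reads of RUNX1 1 (95% interval 2.44 to 2.45) and 3.47% of RUNX1 2 (3.46 to 3.48). They held 0.744% of the reads of IgG 1 (0.739 to 0.750) and 0.506% of IgG 2 (0.503 to 0.509).

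Shared peaks were ranked by the larger of their Poisson p-values in the 2 RUNX1 libraries, not by fold. The first in that order lay on chromosome 17 from 85280201 to 85280850. Its summit held 141 and 170 reads with RUNX1 against 7 and 3 with IgG, or 8.81 ± 1.67 against 0.467 ± 0.425 CPM (SD, n = 2 each), a 23.8-fold difference (95% interval 12.8 to 50.1). Next came chromosome 10 from 7065101 to 7065650, with 140 and 142 RUNX1 reads against 2 and 13 IgG reads, a 14.4-fold difference (8.57 to 26.0). The peak on chromosome 7 from 151632851 to 151633450 had 129 and 139 RUNX1 reads against 7 and 4, an 18.6-fold difference (10.2 to 37.8). On chromosome 5 from 144654251 to 144654700 there were 131 and 169 reads against 10 and 5, a 15.3-fold difference (9.12 to 27.7). On chromosome 7 from 134234551 to 134235000 there were 134 and 176 reads against 5 and 7, a 19.7-fold difference (11.1 to 38.6). The sixth, on chromosome 5 from 108188101 to 108188600, had 132 and 166 reads against 10 and 13, a 9.91-fold difference (6.48 to 15.9). The peak on chromosome 11 from 61416201 to 61416700 had 112 and 144 reads against 6 and 2, a 24.5-fold difference (12.2 to 57.3).

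**Figure D2:**
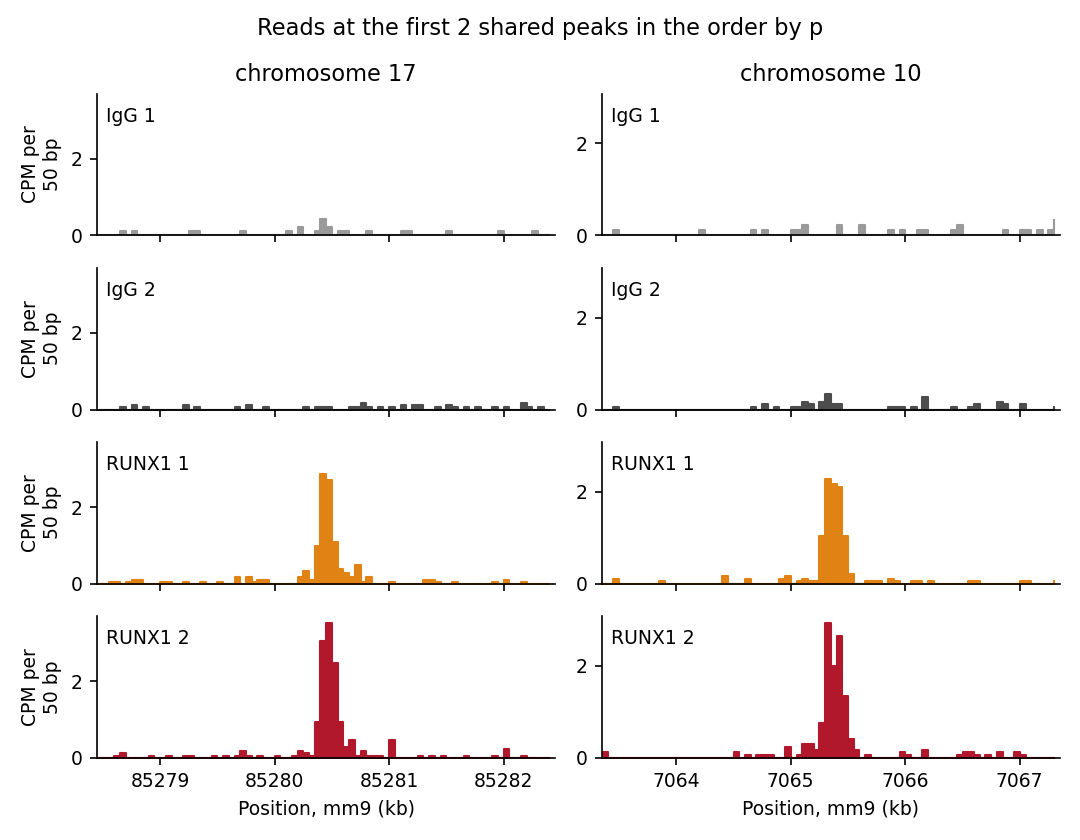
CPM in 50 bp bins (vertical axis, the same scale for the 4 libraries of a column) along mm9 position in kb (horizontal axis) at the first shared peaks in the order by p, on chromosomes 17 and 10. Both RUNX1 libraries rise at the summit, where they hold 141 and 170 reads on chromosome 17 and 140 and 142 on chromosome 10, and the IgG libraries hold 13 or fewer.

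Around the shared summits, taken from the peaks of RUNX1 1, the summit-to-flank ratio was 11.2 in RUNX1 1 (95% bootstrap interval 11.1 to 11.3) and 14.8 in RUNX1 2 (14.63 to 15.02). At the summits of the shared peaks of RUNX1 2 it was 10.7 and 15.6. Each RUNX1 library thus had the higher ratio at summits chosen on its own reads, a selection that the intervals do not cover. At the summits of RUNX1 1 the ratio was also above 1 in the control libraries, at 2.96 in IgG 1 (2.92 to 3.01) and 2.11 in IgG 2 (2.09 to 2.13).

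**Figure D3:**
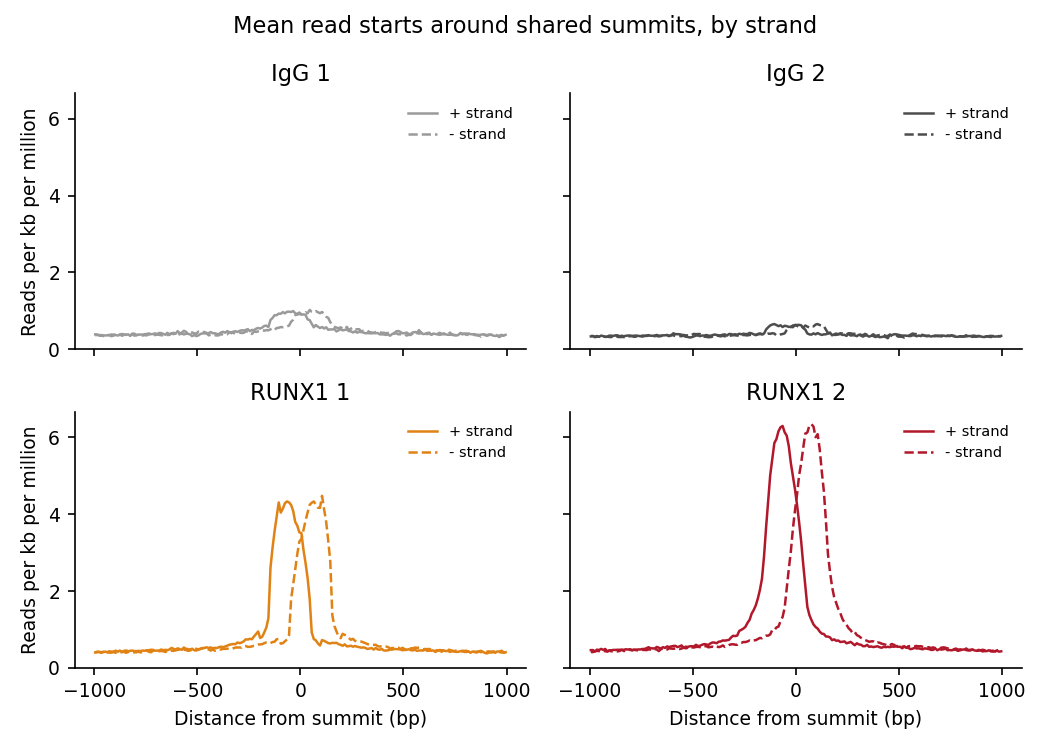
Mean read starts per kb, scaled as CPM (vertical axis) against distance from the shared summits in bp (horizontal axis), with plus-strand reads as solid and minus-strand reads as dashed lines in each of the 4 libraries. Summit-to-flank ratios were 11.2 and 14.8 in the RUNX1 libraries and 2.96 and 2.11 in the IgG libraries.

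Shared peaks were denser on autosomes with more genes. Chromosome 11 had 9.29 shared peaks per Mb and chromosome 19 had 6.93, against 4.29 on chromosome 14 and 4.37 on chromosome 3. Chromosome 7 went against this, with the most genes per Mb of the autosomes (13.3) and 5.78 shared peaks per Mb, fewer than the 6.60 on chromosome 13 with 6.89 genes per Mb. Over the 19 autosomes the density rose with the number of protein-coding genes per Mb (Pearson r 0.755, permutation p 0.0003, adjusted 0.0004; Spearman rho 0.744, permutation p 0.0005, adjusted 0.0005; 4 tests). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.786. With peaks counted per IgG read of the chromosome instead of per Mb, r was 0.860 (permutation p 4e-05, adjusted 8e-05). The X chromosome had 1.03 shared peaks per Mb, and its read depth was 0.351 and 0.362 times the autosomal median in IgG 1 and IgG 2. Counted per 1000000 IgG reads it had 283 shared peaks, below every autosome, of which chromosome 1 had the fewest at 407. The control rate in the peak calls was never set below the genome rate. A site on the X therefore needed a larger excess over its own low background than an autosomal site. Counting per IgG read does not remove this, so these values cannot show that the X had fewer sites.

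**Figure D4:**
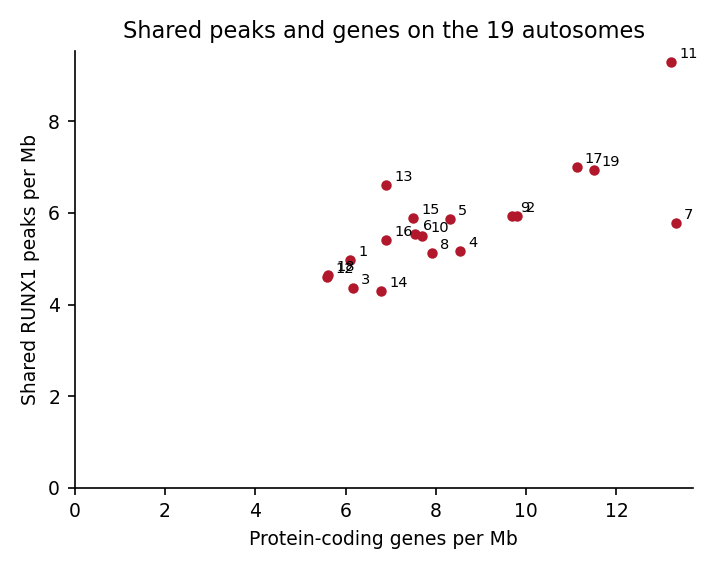
Shared RUNX1 peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis), with 1 point for each of the 19 autosomes, labelled by number. Density ranges from 4.29 on chromosome 14 to 9.29 on chromosome 11.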

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

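The number of reads stacked at a position was left out of the main comparisons. In the RUNX1 libraries it was higher inside shared peaks than elsewhere, by a ratio of 1.174 in RUNX1 1 and 1.177 in RUNX1 2. These ratios exceed those of the control samples, which were 1.04 in IgG 1 and 1.02 in IgG 2. No explanation was tested.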

How the results depend on the processing

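The window counts were the least stable results. Higher and lower windows, 1594 and 39 as reported, were 599 and 13 with scaling by the median ratio over 10 kb bins, 2436 and 69 with TMM, 5157 and 110 with limma trend on log2(CPM + 0.5), 2999 and 0 with DESeq2 (which left 455240 adjusted p-values undefined), and 0 and 0 with limma voom. They were 0 and 0 with the filter at 4 times the genome mean in edgeR (11606 and 33 at an unadjusted p under 0.05), 332 and 6 with no filter other than 1 read, 199 and 0 in 200 bp windows, and 700 and 2 in 1000 bp windows. All reads kept gave 1231 and 101, and reads not moved gave 1296 and 29. Leaving out 1 library gave 0 to 188 higher and 0 to 45 lower, where the lone library of a group is assumed to vary like the other group. Of the higher windows, 599 of 599 with the median ratio, 1554 of 2436 with TMM and 821 of 2999 with DESeq2 were among the 1594. The cause of these shifts was not tested.

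The replicate block gave 25 higher and 2 lower windows. The replicate numbers do not pair the samples by any label, and the deviations of same-numbered libraries correlated at -0.09 over windows and -0.14 over 10 kb bins. A crossed replicate block, chosen after seeing the data, gave 11953 higher and 224 lower, and which numbering matches the libraries, if either, is not known.

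For the 10 named regions, 97 of 153 values from the alternatives stayed past the threshold and 56 did not, with none reversed; values whose adjusted p DESeq2 left undefined, and regions removed by the filter at 4 times the genome mean or in 1000 bp windows, are not counted.

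Peaks in RUNX1 1, RUNX1 2 and shared, 21540, 31012 and 14141 as reported, were 10269, 19481 and 9036 at p at most 1e-08. They were 11244, 20582 and 8141 with libraries thinned to the depth of IgG 1, an alternative chosen after seeing the data, where fewer reads set the lower counts. With the antibodies exchanged at that depth, IgG 1 gave 2995 peaks and IgG 2 gave 1267, and 25 were shared. With all reads kept RUNX1 1 had 33087 and RUNX1 2 had 39340, but the background with the antibodies exchanged rose to 80129 peaks in IgG 1 and 11713 in IgG 2 (601 shared), so the IgG 1 count then exceeded both. The shared count was 12093 to 16597 under the other alternatives. IgG 1 had the fewest kept reads, and windows near 4-fold were mostly missed in simulations. The planned promoter, gene position, motif and gene list results, with their alternatives, were not run.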

Other observations

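The comparisons below were chosen after the data were seen, apart from the test of RUNX1 DNA carried into the IgG libraries, whose prediction was written before its result was seen.

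Shared RUNX1 peaks were grouped along the chromosomes. Bins of 100 kb with 5 or more shared peaks numbered 374, against a mean of 19.28 and at most 31 in 100 random placements weighted by the reads of IgG 2. The fullest bin, on chromosome 5 from 97300001 to 97400000, held 11 shared peaks, and a bin on chromosome 16 from 92800001 to 92900000 held 10. Their read depth in IgG 2 was 2.69 and 2.08 times the genome mean. The placement was changed after its first form had been seen. Without a limit on the weight of a bin, random placements reached 23 peaks in a bin, so the count of 11 does not stand out there. With the weight limited to 3 times the median they reached 9. The count of 374 bins exceeded both forms (mean 20.71 and at most 31 without the limit).

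The IgG libraries held an excess of reads at RUNX1 sites. At 19577 summits shared by the RUNX1 libraries and called without using IgG, the summit-to-flank ratio was 4.11 in IgG 1 and 2.55 in IgG 2. RUNX1 DNA carried into the IgG libraries would give the same IgG excess per RUNX1 excess at weak and strong summits. The excess per RUNX1 2 excess was instead 2.002 times as high in the weakest 4893 as in the strongest 4895 summits for IgG 1 (95% interval 1.87 to 2.15) and 2.09 times for IgG 2 (1.94 to 2.25), which argues against carry-over as the whole source. Easier recovery of open chromatin was not tested, and the design gives no group that would test a biological explanation.

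RUNX1 2 gave 1.44 times as many peaks as RUNX1 1, and 16942 of its peaks were not found in RUNX1 1. Deeper sequencing does not account for this, since RUNX1 2 had 0.9201 times the kept reads of RUNX1 1. A background shared with IgG 1 was tested first with IgG 2 as the only control. The IgG 1 summit-to-flank ratio at peaks of RUNX1 2 alone was 0.9712 times that at shared peaks (95% interval 0.947 to 0.996). This went against a shared background. In those calls, however, shared peaks were higher in all 4 libraries (3.70 against 3.59 in IgG 1, 2.05 against 1.90 in IgG 2). The first test therefore also followed the strength of the sites and cannot decide. A second test, chosen after that, went with a shared background. It compared peaks of RUNX1 2 alone with peaks of RUNX1 1 alone, called without IgG. The IgG 1 to IgG 2 ratio was 1.90 times as high at the former (1.84 to 1.95). In the peaks called against pooled IgG, the IgG 1 ratio was 3.64 at peaks of RUNX1 2 alone (3.58 to 3.71). It was 2.96 at shared peaks (2.92 to 3.01) and 1.78 at peaks of RUNX1 1 alone. The IgG 2 ratio was 1.94, 2.11 and 2.22 in the same order. With 1 test that cannot decide and 1 chosen afterwards, a shared background and a difference in the immunoprecipitations cannot be told apart. No biological explanation was tested.

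Read depth on chromosome 1 stepped up near 117 Mb in all 4 libraries, by 0.74, 0.66, 0.71 and 0.70 on the log2 scale in IgG 1, IgG 2, RUNX1 1 and RUNX1 2, to 1.45 times the autosomal median in IgG 2. It was picked as the largest step of the 20 chromosomes searched. The step on chromosome 4 was of similar size but differed more between libraries (0.72 in IgG 1, 0.48 in IgG 2). Other chromosomes also stepped, such as chromosome 9 (0.62 and 0.46 in IgG 1 and IgG 2) and chromosome 14 (-0.58 and -0.44). Depth on chromosome 1 was not even on either side of the step. In IgG 2 the log2 depth over the autosomal median fell to -0.43 at 141 Mb, after the step. It was 0.69 at 108 Mb, before the step. The trend of the ratio of RUNX1 1 to IgG 2 on depth over other autosomal bins left the 78 distal bins at a median residual of -0.1101 (SD of the other bins 0.0619), which argues against a shared coverage trend as the whole source. After lowering the distal depth by the ratio of 3 copies to 2, the residual was 0.008378. This value follows from the first residual and the slope of the trend (0.203), so it is not a separate test. An extra copy of distal chromosome 1 in these cells remains a hypothesis, found and examined on the same libraries. GC content, which needs the mm9 sequence, was not tested.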
